A study of Lotus japonicus with 12 samples.

How the data were processed

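The data are 12 RNA sequencing libraries from root nodules of the legume Lotus japonicus, 3 libraries for each of 4 groups. The groups are wild-type (WT) plants and cpop1 mutants, each at 10 and 21 days post inoculation (dpi). Per the labels' protocols, seedlings were inoculated with the rhizobium Mesorhizobium loti, RNA was extracted with the RNeasy Plant Mini Kit, and libraries were sequenced on the DNBSEQ platform. The columns of the mutant carry the name hemf2 where the sample titles say cpop1, and each was tied to its sample through the description in the labels. The labels do not say whether the libraries of a group came from separate plants or pots, so p-values measure only the spread between these samples, which may be technical.

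The deposited values are FPKM (fragments per kilobase of transcript, scaled to the sequenced fragments), as the file header names them, with 1 column per library and 2 decimals. HISAT and Bowtie2 2.2.5 are named in the submitters' processing notes with no role given. The genome build, the annotation and the FPKM tool are not given in the sources used here. The table has 29531 rows: 25983 carry IDs beginning with LotjaGi and 3548 carry IDs beginning with BGI_novel. 2 IDs occurred on more than 1 row, 4 rows in all, and each row was kept apart. Because FPKM are relative to each library's total, a change in a few very abundant transcripts shifts all others.

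None of the IDs matched the RefSeq gene table of assembly LjGifu_v1.2, in which 0 of 40429 rows gave a match, so features are reported by ID. For the same reason the level of the mutated gene, which would check the mutant labels, was not analysed here. Of the 33 gene lists fixed before the data were examined, 0 could be applied.

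The depth in reads is unknown. Low FPKM values are multiples of what 1 read is worth, and the most frequent ratio of such values to WT 10 dpi replicate 1 lay between 1.0 and 1.035 across libraries. This comparison used features with values between 0.15 and 0.8 FPKM in both libraries and 0 in at least 7 of the 12 libraries, 56 to 125 features per pair. The totals of FPKM ranged from 985272 to 1224719 per library, and they are not read depths.

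Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, 22249 in all. A linear model with 1 mean per group was fitted to log2(FPKM + 1) of all 12 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend). The model gave 5 comparisons: cpop1 against WT at each age, 21 against 10 dpi in each genotype, and the difference between the genotype effects at the 2 ages. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. In simulated data with 100 genes changed per fold size among 22249, limma recovered 47% of 2-fold and 77% of 4-fold changes at 10 dpi, and 45% and 76% at 21 dpi. The changed genes were drawn only from genes above a minimum mean level and were far fewer than the genes called in the data. Because the adjusted threshold is looser where more genes change, these shares are not the recovery in the data.

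With no names for the IDs, the rule fixed before the data were examined names, for each comparison, the 2 IDs that rose and the 2 that fell most. Each had to pass the adjusted p threshold, with a mean of at least 5 FPKM in the higher group and no overlap between the libraries of the groups compared. The overlap condition was not applied to the difference of effects, which sets no single pair of groups against each other, and its mean was taken in the highest of the 4 groups. The share of total FPKM held by the 20 most abundant genes of each library, ranked within that library, was compared by an exact two-sided permutation test. With 3 against 3 libraries this test cannot give a p under 0.1. The rescaling without the 20 most abundant genes left out a single fixed set, ranked by mean FPKM over all libraries. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for descriptive values and plots.

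Alternatives fixed before the data were examined were other pseudocounts (0.1 and 0.5), no filter or a filter at 5 FPKM, 4 other scalings, a replicate block, only the compared groups in the fit, other variance models, library weights, and each library left out in turn. Alternatives added after seeing the data were the 10 dpi comparison fitted to its own groups without WT replicate 3, the share held by the 3 most abundant genes, and the overlaps of the age changes under the other scalings and without WT 10 dpi replicate 3.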

Results

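The transcriptomes of root nodules, the organs in which legumes house nitrogen-fixing rhizobia, were compared between WT and cpop1 plants of Lotus japonicus. According to the series title, CPOP1 is an enzyme of heme synthesis, and the comparison addressed which pathways depend on it in young (10 dpi) and mature (21 dpi) nodules. Each of the 4 groups had 3 libraries. Between 18486 and 20623 features per library reached 1 FPKM. The read depth is unknown.

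Replicates of 3 groups resembled each other closely, with correlations across genes of log2(FPKM + 1) of 0.986 to 0.988 in WT at 21 dpi, 0.968 to 0.986 in cpop1 at 10 dpi and 0.989 to 0.991 in cpop1 at 21 dpi. In WT at 10 dpi they ranged from 0.839 to 0.989. Replicate 3 of that group had a mean correlation of 0.843 with its own replicates and of 0.935 with the cpop1 10 dpi libraries. It was kept under its label in all comparisons, and the count without it is given with each comparison. Genes are not independent replicates, so these correlations describe the libraries only.

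**Figure D1:**
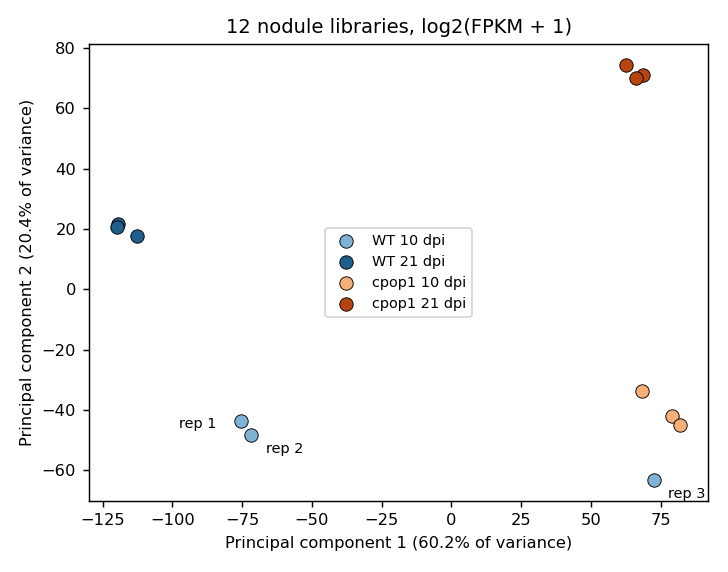
Principal components 1 and 2 (60.2% and 20.4% of the variance) of log2(FPKM + 1) for the 12 libraries, 1 point per library, colored by group. WT 10 dpi replicate 3 lies at 72.5 on component 1, near the cpop1 10 dpi libraries (68.2 to 82.0), whereas replicates 1 and 2 lie at -75.6 and -71.8.

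At 10 dpi, 5053 of 22249 tested genes (22.7%) differed between cpop1 and WT nodules, 2542 of them higher and 2511 lower in cpop1 (limma, adjusted p under 0.05). The share higher was 50.3% as deposited and lay between 45.4% and 52.3% under other scalings. Of these, 1470 were at least 2-fold higher and 918 at least 2-fold lower. BGI_novel_G003607 rose from 0.8 ± 0.368 FPKM in WT to 198 ± 70.8 in cpop1 (SD, n = 3 libraries each), a log2 change of 6.75 ± 0.27 (SE; limma adjusted p = 1e-07). LotjaGi2g1v0157900 rose from 2.17 ± 3.39 to 209.7 ± 58.3 FPKM, by 6.56 ± 0.65 on the log2 scale (limma adjusted p = 0.000105). LotjaGi3g1v0078750 stood at 339.9 ± 37.2 FPKM in WT and at 0.633 ± 0.31 in cpop1, a log2 change of -7.72 ± 0.18 (limma adjusted p = 6.76e-09). LotjaGi4g1v0026000 fell from 3345 ± 685 to 29.2 ± 12.9 FPKM, a log2 change of -6.86 ± 0.33 (limma adjusted p = 4.57e-07). WT replicate 3 was at 1.21, 6.08, 377 and 2571 FPKM for these IDs, in the order named. The rule allowed no overlap between the groups, so its place on the WT side was fixed by the selection.

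The number of calls at 10 dpi depended on single libraries. Without WT 10 dpi replicate 3, 14224 genes were called. Without WT replicate 1 or 2 the counts were 2246 and 2082, and without cpop1 10 dpi replicate 2 or 3 they were 2368 and 2958. The groups did not overlap in 28.5% of genes at 10 dpi, where chance gives 10%. A fit to the 6 libraries of this age alone called 681 genes, and library weights gave 18582.

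At 21 dpi, 12821 genes (57.6%) differed between the genotypes, 6498 higher and 6323 lower in cpop1, with 4033 and 3237 of them changed at least 2-fold. Which direction held the majority depended on the scaling: 43.8% of the changed genes were higher in cpop1 after a shift to a common median, 47.8% after quantile normalization, 44.7% after rescaling to a common total and 56.3% after rescaling without the 20 most abundant genes, against 50.7% as deposited. LotjaGi6g1v0203100 rose from 0.0833 ± 0.076 FPKM in WT to 161 ± 21.0 in cpop1, a log2 change of 7.22 ± 0.89 (limma adjusted p = 0.000108). LotjaGi5g1v0292900 rose from 0.143 ± 0.08 to 168 ± 20.9 FPKM, by 7.21 ± 1.08 on the log2 scale (limma adjusted p = 0.00033). Both IDs were at 0.23 FPKM or less in WT 10 dpi replicates 1 and 2 and at 17.4 and 37.9 FPKM in replicate 3. LotjaGi4g1v0196300 was at 1104 ± 380 FPKM in mature WT nodules and stood at 0.12 ± 0.12 in cpop1, a log2 change of -9.9 ± 0.39 (limma adjusted p = 1.14e-07). LotjaGi2g1v0177300 fell from 1001 ± 232 to 0.0467 ± 0.081 FPKM, a log2 change of -9.88 ± 0.32 (limma adjusted p = 1.03e-07). The groups did not overlap in 76.4% of genes, where chance gives 10%. Without WT 10 dpi replicate 3, which enters only the shared estimate of the spread, 15842 genes were called, and without other single libraries the lowest count was 10661.

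**Figure D2:**
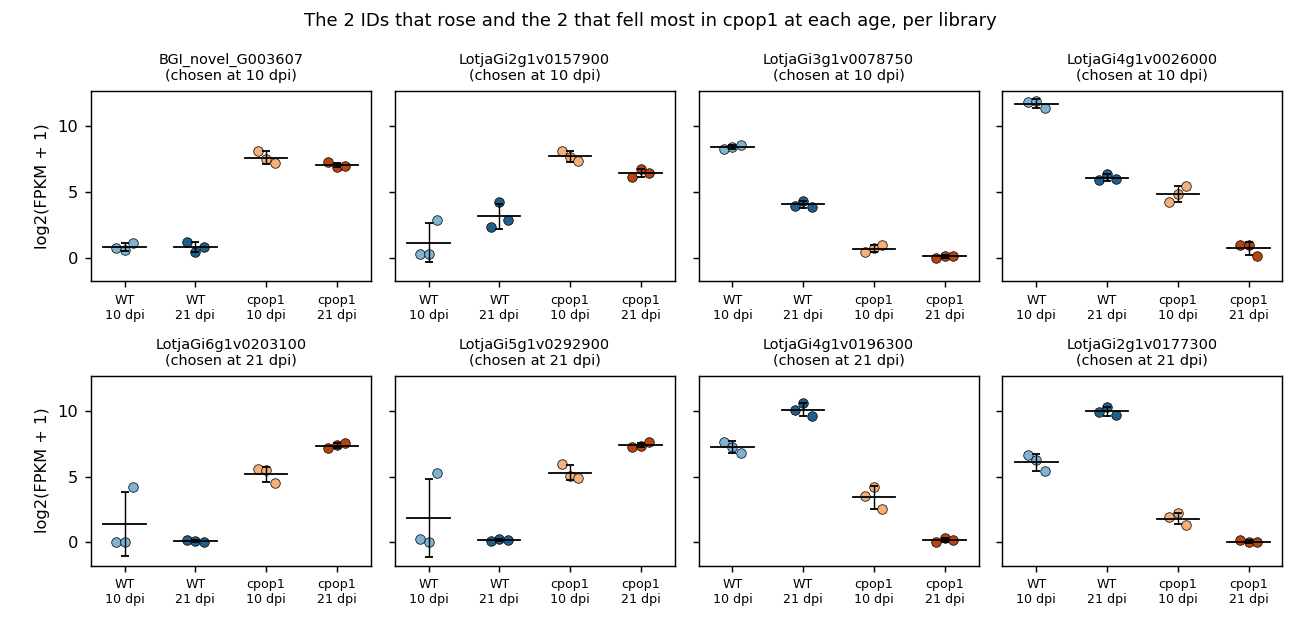
Level of the 2 IDs that rose and the 2 that fell most in cpop1 at each age, chosen by the rule for named IDs, as log2(FPKM + 1) per library (points), with the mean (line) and SD (bars) of the 3 libraries of each group. The upper row was chosen at 10 dpi and the lower row at 21 dpi. LotjaGi4g1v0196300 is near 0 in all 3 cpop1 libraries at 21 dpi.

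The genotype effects at the 2 ages, which share no library, had a Pearson correlation of 0.66 and a Spearman correlation of 0.65 across genes. Of the genes called at both ages, 1588 were higher and 1754 lower in cpop1 at both. Independent lists of the same lengths would share 742 and 714. The calls of both ages use the same estimate of each gene's spread. Genes of low spread can therefore add to the overlap, and these counts are no exact chance level. Another 161 genes were higher at 10 and lower at 21 dpi, and 124 the reverse. The Pearson correlation lay between 0.57 and 0.73 when single libraries were left out, which always kept WT 10 dpi replicate 1 or 2. With WT replicate 3 as the only WT library at 10 dpi it was 0.05 (Spearman -0.02), against 0.73 with replicates 1 and 2. The agreement between the ages thus rested on WT replicates 1 and 2.

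For 4441 genes (20%) the genotype effect itself differed between 21 and 10 dpi, with 2161 differences positive and 2280 negative (limma interaction, adjusted p under 0.05). LotjaGi1g1v0066900 had a difference of effects of 5.92 ± 0.63 on the log2 scale: at 21 dpi it was at 3.15 ± 0.747 FPKM in WT and 167 ± 14.8 in cpop1, and at 10 dpi at 52.5 ± 32.9 and 35.2 ± 19.4. LotjaGi6g1v0282700 had a difference of 5.36 ± 1.24 (limma adjusted p = 0.0134). Its WT 10 dpi libraries were far apart, from 11.5 FPKM in replicate 1 to 273 in replicate 3. LotjaGi1g1v0539500 (-7.09 ± 1.27) was at 306.7 ± 41.7 FPKM in mature WT nodules and at 0.88 ± 0.928 in mature cpop1 nodules, with 144 ± 101 and 125 ± 127 in young ones. LotjaGi3g1v0246500_LC (-7.07 ± 0.54) was at 79.6 ± 9.05 and 0.343 ± 0.345 FPKM in mature WT and cpop1 nodules, and at 36.3 ± 3.73 and 92.5 ± 55.9 in young ones. Without WT 10 dpi replicate 3 the count was 8647, without cpop1 21 dpi replicate 1 it was 2858, and library weights gave 13318. When FPKM were rescaled without the 20 most abundant genes, 61.8% of the differences called were positive, against 48.7% as deposited.

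Between 10 and 21 dpi, 7956 genes (35.8%) changed in WT nodules, 2523 higher and 5433 lower at 21 dpi. BGI_novel_G000720 rose from 33.5 ± 28.2 to 2368 ± 917 FPKM (log2 change 6.32 ± 0.61) and LotjaGi5g1v0043800_LC from 57.3 ± 24.3 to 4129 ± 1029 (6.21 ± 0.29). In cpop1 nodules of 21 dpi these IDs stood at 32.5 ± 18.0 and 7.68 ± 1.38 FPKM. LotjaGi3g1v0312900 fell from 449 ± 525 to 2.71 ± 0.465 FPKM (-6.26 ± 0.60). LotjaGi2g1v0200400 fell from 90.3 ± 73.4 to 0.203 ± 0.076 FPKM (-5.96 ± 0.43). In cpop1 the means of these 2 IDs were also lower at 21 than at 10 dpi, at 152 against 950 FPKM for LotjaGi3g1v0312900 and 9.41 against 154 for LotjaGi2g1v0200400. In WT replicate 3 at 10 dpi, LotjaGi3g1v0312900 was at 1054 FPKM, against 137 and 155 in the other replicates. The groups did not overlap in 49.2% of genes, where chance gives 10%. Without WT 10 dpi replicate 3, 9954 genes were called. A fit to the WT libraries alone called 3535 genes, and library weights gave 14465.

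In cpop1 nodules, 6574 genes (29.5%) changed between 10 and 21 dpi, 1787 higher and 4787 lower. LotjaGi5g1v0078900 rose from 2.7 ± 0.837 to 114 ± 6.43 FPKM (log2 change 4.98 ± 0.30), and in WT it was at 4.09 ± 2.68 and 5.79 ± 1.12 FPKM. BGI_novel_G000769 rose from 2.21 ± 0.988 to 69.4 ± 13.3 FPKM (4.49 ± 0.95). LotjaGi4g1v0268200_LC fell from 620 ± 317 to 0.887 ± 0.372 FPKM (-8.24 ± 0.52). LotjaGi1g1v0539200 fell from 369 ± 80.4 to 2.13 ± 0.845 FPKM (-6.90 ± 1.15). In WT the means at 10 and 21 dpi moved the same way: 24.2 and 201 FPKM for BGI_novel_G000769, 184 and 61.2 for LotjaGi4g1v0268200_LC, and 208 and 0.25 for LotjaGi1g1v0539200. For the last of these, WT 10 dpi replicate 3 was at 599 FPKM, against 13.89 and 10.25 in replicates 1 and 2. The groups did not overlap in 58.3% of genes, where chance gives 10%. Without WT 10 dpi replicate 3, which enters only the shared estimate of the spread, 11565 genes were called. Without cpop1 10 dpi replicate 2 the count was 4299, and without cpop1 21 dpi replicate 1 or 3 it was 4351 and 4253. A fit to the cpop1 libraries alone called 10561 genes, and library weights gave 14980.

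The direction of the age changes depended on the scaling. The median log2 change over all tested genes was -0.226 in WT and -0.197 in cpop1 as deposited. Of the genes changed with age in WT, 31.7% were higher at 21 dpi with FPKM as deposited, 63.6% after a shift of each library to a common median, 52.1% after quantile normalization and 21.4% after rescaling to a common total. In cpop1 the corresponding shares were 27.2%, 56.1%, 51.1% and 15%, and 38.6% after rescaling without the 20 most abundant genes. Under the median shift the median change was 0.13 in WT and 0.08 in cpop1.

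**Figure D3:**
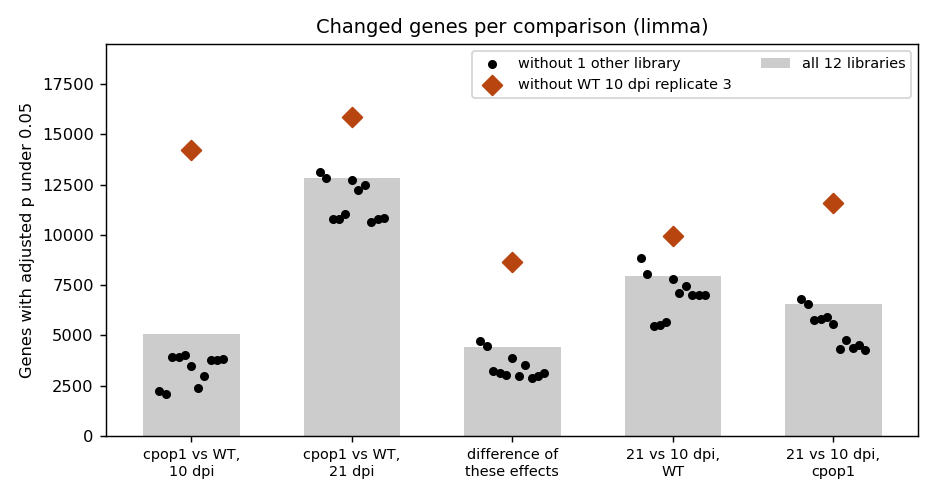
Number of genes with an adjusted p under 0.05 (limma) in each comparison, with all 12 libraries (bars), without 1 other library (black points) and without WT 10 dpi replicate 3 (diamonds). The highest count in each comparison is the one without that replicate, 14224 for the genotypes at 10 dpi.

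The age changes of the genotypes, which share no library, had a Pearson correlation of 0.3 across genes. In both genotypes 1978 genes fell with age and 469 rose, where independent lists would share 1169 and 203. Here too the shared estimate of each gene's spread can add to the overlaps. Of the 5433 genes that fell with age in WT, 3135 were higher and 377 lower in cpop1 than in WT at 21 dpi, where independent lists would share 1587 and 1544. Of the 2523 genes that rose with age in WT, 1948 were lower and 111 higher in cpop1 at 21 dpi, where independent lists would share 717 and 737. The sizes of these sets depended on the scaling, whereas the overlaps in the majority directions exceeded independent lists under each of the 4 other scalings and without WT 10 dpi replicate 3. After the shift to a common median, 857 genes fell and 1326 rose in both genotypes (346 and 773 for independent lists). Of the 2905 genes that then fell in WT, 1850 were higher in cpop1 at 21 dpi, and of the 5080 that rose, 3598 were lower (747 and 1676 for independent lists). With that replicate left out, 3404 genes fell and 1002 rose in both (2411 and 516 for independent lists). Of the 6542 that then fell in WT, 3735 were higher and 1114 lower in cpop1 at 21 dpi, and of the 3412 that rose, 2218 were lower and 566 higher. The WT 21 dpi libraries enter both the WT age change and the genotype effect at 21 dpi. The correlation of the genotype effect at 21 dpi with the WT age change was -0.62, against -0.5 in simulated data with no effect. The covariance was -0.703, against -0.049 simulated. Without WT 10 dpi replicate 3 the correlation was -0.37, weaker than the -0.45 simulated with no effect. The covariance was then -0.361, against -0.022 simulated. The simulated data held no group differences, whereas any real departure of the WT 21 dpi level enters both effects with opposite signs. Such departures alone can push the covariance past the simulated one. They can also push the overlaps of the WT age sets with the genotype effect past independent lists. Neither excess can therefore tell an opposition of the effects from the sharing of WT 21 dpi libraries.

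The same 3 features were the most abundant in every library: LotjaGi5g1v0024700, LotjaGi5g1v0046500 and LotjaGi5g1v0024900, named here after their values were seen. The 20 most abundant genes of each library, which need not be the same genes in all libraries, held 37.1 ± 1.03% of total FPKM in cpop1 and 26.9 ± 1.22% in WT at 21 dpi (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). At 10 dpi the shares of each library's own 20 were 19.7 ± 1.34% and 19.3 ± 3.08% (exact p = 0.8). The 3 most abundant alone held 30.6 ± 1.02% against 16.7 ± 1.28% at 21 dpi and 13 ± 1.34% against 10.6 ± 1.07% at 10 dpi (exact p = 0.1 at both ages). Among them, LotjaGi5g1v0046500 rose from 49617 ± 5377 FPKM in WT to 152173 ± 3902 in cpop1 at 21 dpi, a log2 change of 1.62 ± 0.38 (limma adjusted p = 0.0044). LotjaGi5g1v0024700 stood at 97356 ± 6272 FPKM in WT and 164077 ± 12690 in cpop1 at 21 dpi, a log2 change of 0.75 ± 0.47 (limma adjusted p = 0.193). LotjaGi5g1v0024900 stood at 35810 ± 1443 and 51401 ± 3427 FPKM, a log2 change of 0.52 ± 0.31 (limma adjusted p = 0.177). Neither passed the test, whose spread is shared over all groups and drawn toward that of other genes. Not passing therefore does not show equal levels.

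**Figure D4:**
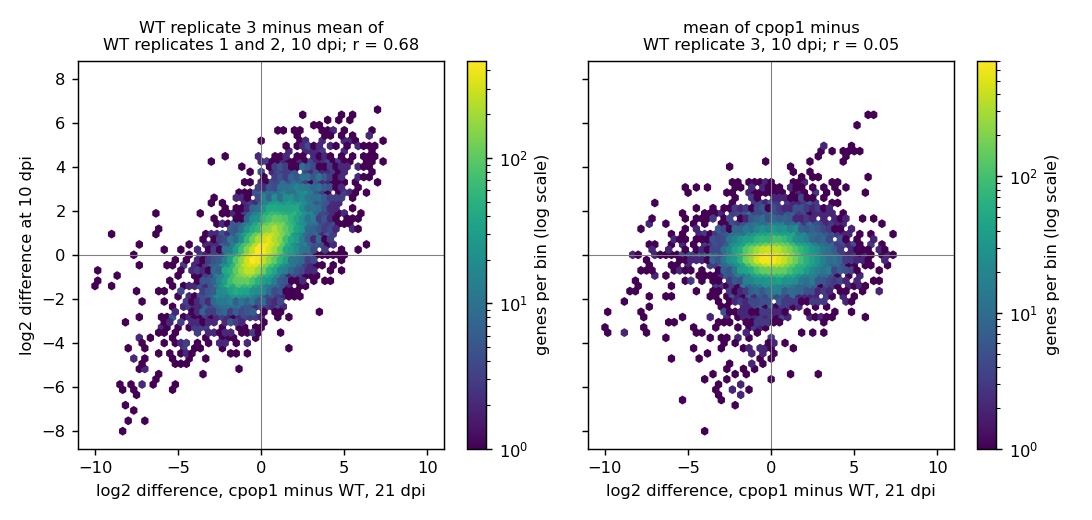
Each panel plots the log2 difference of cpop1 minus WT at 21 dpi (x axis) against a log2 difference at 10 dpi (y axis) for the 22249 tested genes, with color giving genes per bin on a log scale. On the left, the gap of WT replicate 3 to WT replicates 1 and 2 has a Pearson correlation of 0.68 with the effect at 21 dpi, and on the right, cpop1 minus WT replicate 3 has one of 0.05.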

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

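The tests of a wrong label, of a mixture and of a shared batch, and the sorting of splits by the age they mix, were chosen after the results they concern had been seen, and the test of an earlier stage was fixed before, apart from its exchange of replicates.

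A test of the difference itself singled out 4441 genes whose genotype effect differed between 21 and 10 dpi. The IDs named for this difference are LotjaGi1g1v0066900 (5.92), LotjaGi6g1v0282700 (5.36), LotjaGi1g1v0539500 (-7.09) and LotjaGi3g1v0246500_LC (-7.07), on the log2 scale. Of 100 splits of the libraries within each age, the real one included, 7 gave as many genes as the real split, with up to 14110 in another split. The other 6 of these mixed the genotypes at 10 dpi only and kept them parted at 21 dpi, so the effect at 21 dpi stayed inside the difference and these splits say nothing of chance. The 6 splits that mixed the genotypes at 21 dpi only gave at most 110 genes, and the 82 that mixed them at both ages gave at most 1. Splits that mix genotypes also remove the effects common to both ages, so these counts do not decide on chance either.

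At 10 dpi the real split of the 6 libraries gave 5053 genes and the highest other split gave 6271, so 2 of the 10 splits gave as many. That other split set cpop1 replicate 1 with WT replicates 1 and 2 against cpop1 replicates 2 and 3 with WT replicate 3. For the genotypes at 21 dpi the real split gave 12821 genes and the highest other 0, for the WT age change 7956 and 0, and for the cpop1 age change 6574 and 1. The real split was thus the only 1 of 10 to give as many genes in these comparisons. With 10 splits no share under 0.05 can be reached.

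WT replicate 3 at 10 dpi lay nearer the cpop1 10 dpi libraries (mean correlation 0.935) than its own replicates (0.843), and its gap to them had an SD of 1.16 across genes, against 0.31 between replicates 1 and 2. A cpop1 library carrying a WT label stays open: 138 genes parted the 6 WT from the 6 cpop1 libraries by at least 2-fold, against 63, 5 and 20 when a cpop1 10 dpi library took its place, but 27 features present or absent by genotype in the other 11 libraries placed this one with cpop1 and 6 with WT. A mixture with cpop1 nodule RNA as the cause of the whole pattern was not decided, because the transcripts that would show it disagree. The median position of the library on genotype-parting genes was 0.99, where 0 is WT and 1 is cpop1. A mixture at that position would bring cpop1 transcripts near their cpop1 level. Among 9 transcripts steady in cpop1 and below 0.1 FPKM in the other 5 WT libraries, 5 were below 0.1 FPKM here. The median was 0% of the cpop1 level, and 4 were present, up to 258%. The 5 absent transcripts also go against a wrong label, whereas the position goes with it. A mixture behind part of the pattern was not decided either. For an earlier nodule stage, the test as fixed beforehand counted against it. The gap to replicate 2 correlated -0.07 with the WT age change taken from replicate 1, above the bound of -0.1. With replicates 1 and 2 exchanged, which was added later, the correlation was -0.11, just past that bound, so the 2 values together leave it undecided. Both fell well short of the stronger negative correlation set beforehand as the sign of an earlier stage. On principal component 2, all 10 dpi libraries were negative and all 21 dpi libraries positive. This library was the lowest there, at -63.2, and the next lowest was WT 10 dpi replicate 2 at -48.3. That was seen afterwards and is no test of stage, which stays undecided. A growth, harvest or library batch shared with the cpop1 libraries also stays open and cannot be told apart from biology, because the gap correlated 0.68 with the genotype effect at 21 dpi, with which it shares no library, and no label gives a batch.

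The measures for 2 of these explanations were replaced after their first outcome was known. For the mixture, the first bound asked that the highest of the 9 shares be under 5%. It was 258%, which that bound alone would have counted as a fit, although a mixture asks for a common share in all 9. The median then used in its place would have counted against a mixture. The first bound was restored, and by that bound members on both sides of it are now read as deciding nothing. Setting the 5 absent transcripts against the position of the library, as above, uses the same shares and decides no more than that bound. It was also made with these outcomes in view. For the wrong label, the first measure was the percent of genotype-parting genes on the WT side, which was 12.6% here, at most 6.1% in a cpop1 10 dpi library, and 99.7% and 99.6% in WT replicates 1 and 2. The median position of the library on these genes was 0.99, where 0 is WT and 1 is cpop1, against 0.93 to 1.0 in the cpop1 libraries. By this measure the library lies with cpop1, whereas the 138 parted genes go against a wrong label, so the measures disagree. The count of 27 against 6 features was added to the bound last, also with its outcome in view.

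Of the 12821 genes changed at 21 dpi, 81.3% had the sign of the gap of WT replicate 3 to its replicates, and 52.0% the sign of cpop1 minus WT replicate 3 at 10 dpi.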

How the results depend on the processing

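The fit without WT 10 dpi replicate 3 in the 10 dpi groups alone and the share of the 3 most abundant genes, like the overlaps of age changes under other settings, were chosen after seeing the data. All 500 values of the 20 named IDs under the alternatives kept their direction and their side of the threshold, with a highest limma adjusted p of 0.0362. These IDs were picked from the same data as the largest changes past the threshold. That outcome was therefore likely beforehand and says little of other genes. Other pseudocounts, filters, scalings and variance models kept each count within 1.5 times. This holds for the totals, not for the genes called or their direction. After the shift to a common median, 5428 of 7985 genes called with age in WT were also called as deposited. In cpop1 this held for 4435 of 6033. With only the compared groups in the fit, 681 genes were called between genotypes at 10 dpi, 3535 with age in WT and 10561 with age in cpop1. With library weights the counts were 18582 between genotypes at 10 dpi, 13318 for the difference of effects, 14465 with age in WT and 14980 with age in cpop1. The 10 dpi groups alone without WT replicate 3 gave 12559. Fits to fewer groups called fewer genes where they held that replicate and more where they did not (16239 between genotypes at 21 dpi), so fewer libraries alone does not account for the moves. For the library weights the cause was not tested.

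With single libraries left out, counts ranged from 2082 to 14224 (genotypes, 10 dpi), 10661 to 15842 (genotypes, 21 dpi), 2858 to 8647 (difference), 5476 to 9954 (age, WT) and 4253 to 11565 (age, cpop1). The correlation of the genotype effects ranged from 0.57 to 0.73, and was 0.05 with WT replicate 3 as the only WT library at 10 dpi. The highest count in each range, and the 0.73, came without WT 10 dpi replicate 3. The cpop1 minus WT share of the 20 most abundant genes ranged from 9.59 to 10.8 percentage points at 21 dpi and from -1.4 to 1.28 at 10 dpi. At 10 dpi it turned from 0.384 to -1.4 without WT replicate 3, to -0.387 without cpop1 replicate 3 and to -0.597 over 100 genes. At 21 dpi the difference of 10.2 became 12.1 over 10 genes, 6.08 over 100 and 14 over 3.

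With a replicate block the counts were 4849 (genotypes, 10 dpi), 12817 (genotypes, 21 dpi), 4123 (difference), 7724 (age, WT) and 6337 (age, cpop1). The numbers are not shown to pair the samples: over 18 pairs of equal number the correlation of deviations ran from -0.12 to 0.27, with 4 over 0.1, and 6 of 12 libraries correlated best with their own number. The difference of effects uses all groups and has no fit to fewer. The alternatives for the mutated gene and the gene lists were not run, since no ID was paired with a name. Read depth is unknown, so no counting limit is given.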

Other observations

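All genotype-wide and ID-form counts here were chosen after seeing the data, as were the delayed maturation test and the simulation without WT replicate 3; the tests of shared libraries, of WT replicate 3 alone and of ID order were fixed before their outcomes were seen.

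Some features parted the genotypes in all 12 libraries, WT 10 dpi replicate 3 included. At 1 FPKM or more in all 6 cpop1 libraries and below 0.1 FPKM in all 6 WT libraries there were 6 features, 5 of them with IDs beginning with BGI_novel, and there were 0 the other way. BGI_novel_G001960 had 17.59 to 30.04 FPKM in cpop1 and was listed at 0 in every WT library. Over all tested genes, 2402 did not overlap between the 6 WT and the 6 cpop1 libraries, 876 higher and 1526 lower in cpop1, where chance gives 48. The highest of the other splits among 462 gave 2236. With a gap of at least 2-fold there were 77 genes higher and 61 lower.

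WT 10 dpi replicate 3 had presence patterns that no other library matched. In the other 5 WT libraries 17 features (15 of them BGI_novel) reached 1 FPKM and were below 0.1 FPKM in this replicate and in all cpop1 libraries, and 10 features (1 BGI_novel) showed the reverse. For each of the 11 other libraries, treated the same way within its genotype, the highest counts were 1 and 1.

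No group of IDs by the form of the ID stood apart in every test. With camera and an estimated correlation between genes the lowest adjusted p was 0.737, and with fry it was 0.0689, over 4 groups and 5 comparisons. With a preset correlation of 0.01 some groups passed camera. The 2957 tested BGI_novel IDs had a median log2 change of -0.25 in cpop1 at 10 dpi and -0.34 at 21 dpi, against 0.06 and 0.10 for other genes (camera adjusted p = 0.00317 and 0.00605). The 2456 tested IDs ending in LC had medians of -0.20 and -0.25, against 0.05 and 0.09 (camera adjusted p = 0.0164 and 0.0458). With age, 23 IDs with the letter M had a median of 0.56 in WT, against -0.23, and 0.60 in cpop1, against -0.20 (camera adjusted p = 0.00195 and 0.000416). The BGI_novel IDs with age in WT had a median of -0.01, against -0.26 (camera adjusted p = 0.00212). In cpop1, 33 IDs with the letter C had a median of 0.33 with age, against -0.20 (camera adjusted p = 0.0164). All of these had an adjusted p of 0.737 with an estimated correlation. What these letters stand for is not given in the sources used here.

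The genotype effect at 21 dpi ran against the age change of WT nodules, with a correlation of -0.62 across genes. Noise of single WT 21 dpi libraries is argued against as the whole cause. With replicate 1 in one effect and replicates 2 and 3 in the other, the correlation was -0.59. What these libraries have in common stays in both effects with opposite signs, so the split cannot tell whether the sharing itself gives the correlation. Without WT replicate 3 at 10 dpi the correlation was -0.37, against -0.45 simulated with no effect. It was -0.33 with the WT 21 dpi libraries also split, so a part that comes from WT 10 dpi replicate 3 alone stays open. A delayed maturation of cpop1 nodules was not decided: the slope of the cpop1 age change on the WT age change was 0.27, and 0.31 without WT replicate 3, but nearly any partly shared age change gives a slope between 0 and 1. Genes that fell in WT (median -1.0) had a median age change of -0.44 in cpop1, and genes that rose in WT (median 0.87) had one of 0.06, with 469 rising and 298 falling in cpop1.

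Genes called between the genotypes lay next to each other in ID order more often than chance order gives. Of the genes called at 21 dpi, 32.18% were followed by an ID called in the same direction, against a mean of 29.26% and a highest value of 30.77% in 1000 shuffles. At 10 dpi the share was 14.35%, against 11.62% and 13.16%. For the 97 ordered genes that parted the genotypes by at least 2-fold in all 12 libraries it was 2.06%, within the shuffled range (mean 0.26%, highest 3.09%). No explanation for this order was tested.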
